A study of Mus musculus with 12 samples.

How the data were processed

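Total RNA from flash-frozen mouse liver was sequenced in 12 libraries, which the labels assign to 4 groups of 3 by diet (LF or HF) and genotype (TSP1 floxed, or TSP1 knockout in macrophages). RNA was extracted with the RNeasy kit and the libraries were made by BGI with its standard protocol. Genome build mm9 is named in the submitters' processing notes. The aligner, the counting tool, their versions and the annotation are not given in the sources used here.

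Each library came as 1 deposited file of estimated counts (expected counts), which per the file headers have the column layout of RSEM and are not scaled. Of these values, 87.0 to 88.1% are whole numbers, depending on the library. The FPKM values in the same deposited files were computed by the authors with scaling to effective gene length and to the number of fragments. The files list 14527 to 15329 genes each and no gene under 0.01 FPKM, so the 3825 genes absent from at least 1 file were taken as 0 there. Gene symbols came from the gene numbers in the files, and 16210 of 16239 named genes (99.8%) had a type in the RefSeq gene table. A further 1229 loci without a gene name, holding 6.65 to 17.33% of the estimated counts, were left out of library sizes and tests and kept in an alternative. Positions are not printed because the reference annotation used here follows another build than the files.

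Libraries held 16131506 to 16536016 estimated counts in all, and named genes took 13336969 to 15080378 of them. Estimated counts were rounded and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1): TMM factors, filterByExpr with the 4 groups (12587 genes), trended dispersions and quasi-likelihood F tests, with 1 mean per group over all 12 libraries. There were 6 comparisons: HF against LF in each genotype, knockout against floxed on each diet and averaged over diets, and the interaction. Adjusted p-values are Benjamini-Hochberg values from edgeR, over all genes unless given as over the list alone, and calls are at a false discovery rate of 5%. The standard error of each log2 fold change came from the edgeR fit. Exact permutation p-values for 3 genes used log2(FPKM + 1) in the 6 libraries compared. The biological coefficient of variation over all genes was 34.8%.

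Before the data were examined, 34 gene lists of metabolic and stress pathways, immune responses and cell type markers were fixed. The 33 lists with at least 3 tested members were tested with limma's camera on log2 CPM, counts scaled to library size (prior count 2), at a preset inter-gene correlation of 0.01, with adjusted p-values from limma over the 33 lists. The same lists were tested with the correlation estimated from the residuals and with fry. Some lists lost members to the filter on low counts: 6 of 11 neutrophil markers and 8 of 14 female-biased genes were tested. A gene near 0 in 1 group can pass this filter through a group where it is high. Counts of members below cover the tested ones only. Groups, comparisons, lists, target genes and the first set of alternatives were fixed before the data were examined. Genes were named by rule: the target genes; where fewer than 3 genes passed in a comparison, the 3 protein-coding genes of smallest p in each direction; and, for the HF effect in floxed libraries and the genotype on HF, the 2 members of smallest p in the called direction of each called list. Genes named only by an accession or a serial number were skipped. A few further genes are given as levels only, and 1 gene named by this rule is not reported here.

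The first set of alternatives held DESeq2 1.42.0, its size factors in edgeR, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with at least 1 FPKM in 3 libraries (10533 genes), no filter, and at least 10 counts in 3 libraries. It also held a fit of the compared groups only, replicate number as a replicate block, limma voom with sample weights, each library left out, HF floxed replicate 3 and HF knockout replicate 1 left out together (their files are named in another form), and a test against a change of 1.5-fold. Alternatives added after the data were seen averaged near-identical libraries, used a clock gene score as a covariate, used the 8 libraries with low Dbp, left out HF knockout replicate 2 and kept loci without a gene name.

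The pipeline was tested on simulated counts of 12587 genes with 200 changed genes. For HF against LF in floxed libraries edgeR called 26.9% of genes changed 2-fold, 74.6% of those changed 4-fold and 86.4% of those changed 8-fold, with 7 false calls. For knockout against floxed on HF the shares were 19.4, 68.7 and 87.9% (2 false calls) and for the interaction 4.5, 49.3 and 78.8% (3 false calls). DESeq2 made 41, 30 and 31 false calls in the same order. A list of 22 members shifted 2-fold was found by camera, by camera with an estimated correlation and by fry in all 3 comparisons. Genes were drawn independently of each other, with the same dispersion in all 4 groups. The simulation therefore does not cover lists with correlated members or the larger spread of the HF knockout libraries.

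For genes with 0 counts in a group, folds are lower bounds against a floor of 3 counts over the group; such bounds cover counting error only. Sharing of libraries between comparisons was simulated in 20 draws of unchanged groups, again with independent genes and the same dispersion in all groups. Transcripts of named gene copies were aligned with BLAST 2.17.0. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Histology, physiology and isolated cells were not analysed here.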

Results

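The data comprised 12 RNA-seq libraries of mouse liver (strain 129/B6, 10 months of age) in 4 groups of 3. Mice carried a floxed gene for thrombospondin 1 (TSP1), a secreted matrix protein, or lacked it in macrophages, and each genotype was kept on an LF or an HF diet for 8 months. The groups are named LF floxed, LF knockout, HF floxed and HF knockout, and the study asked what TSP1 from macrophages does in fatty liver disease of obesity. In all, 12587 genes were tested, and group values below are means ± SD of the 3 libraries. The labels give replicate numbers without naming animals, so p-values measure the spread between these libraries, which can be technical in part. LF knockout replicates 2 and 3, and HF floxed replicates 1 and 2, were near-identical, and p-values of comparisons with a pair that is 1 animal would be too small. The biological coefficient of variation was 28.1% in LF floxed, 23.3% in LF knockout, 26.4% in HF floxed and 52.6% in HF knockout. The 4 Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were present in all 12 libraries, at 0.6 FPKM or more. Every library thus held RNA of male mice, which argues against female libraries as the source of the changes in female-biased and male-biased genes below.

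Thbs1 (gene 21825), the gene encoding TSP1, was not lower in the libraries labelled knockout. Its mean was 0.08 ± 0.0265 FPKM in LF floxed, 0.393 ± 0.271 in LF knockout, 0.603 ± 0.254 in HF floxed and 1.07 ± 0.795 in HF knockout. The single libraries labelled knockout held 0.08, 0.55 and 0.55 FPKM on LF and 0.16, 1.42 and 1.63 FPKM on HF. Whole liver holds other cells that keep the gene, so these values neither show nor exclude its loss from macrophages, and every direction below rests on the genotype as labelled. Between genotypes on HF the log2 difference was 0.95 (SE 0.73, edgeR adjusted p = 0.78, two-sided exact permutation p = 0.6). In floxed libraries it was 2.64 between diets (SE 0.84, a 6.23-fold difference, edgeR adjusted p = 0.289). There all 3 HF libraries lay above all 3 LF libraries, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows.

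Smpdl3b (gene 100340), which encodes a sphingomyelin phosphodiesterase-like protein, was named before the data were examined from what is known of the study. The published study may rest on these same libraries, so the values below may not be independent of the choice of this gene. Smpdl3b averaged 0.347 ± 0.465 FPKM in LF floxed, 0.21 ± 0.0854 in LF knockout, 0.303 ± 0.199 in HF floxed and 1.67 ± 0.431 in HF knockout. The HF knockout libraries, at 1.26, 2.12 and 1.64 FPKM, all lay above the other 9. The difference between genotypes on HF was 5.95-fold (log2 2.57, SE 0.83) and did not pass correction over all genes (edgeR adjusted p = 0.598). The two-sided exact permutation p was the smallest possible, 0.1. Lyz2 (gene 17105), a lysozyme of macrophages and neutrophils, averaged 52.1 ± 14.9 FPKM in HF floxed and 14 ± 12.1 in HF knockout, a 3.08-fold lower level (log2 -1.62, SE 0.8) that did not pass either (edgeR adjusted p = 0.684).

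**Figure D1:**
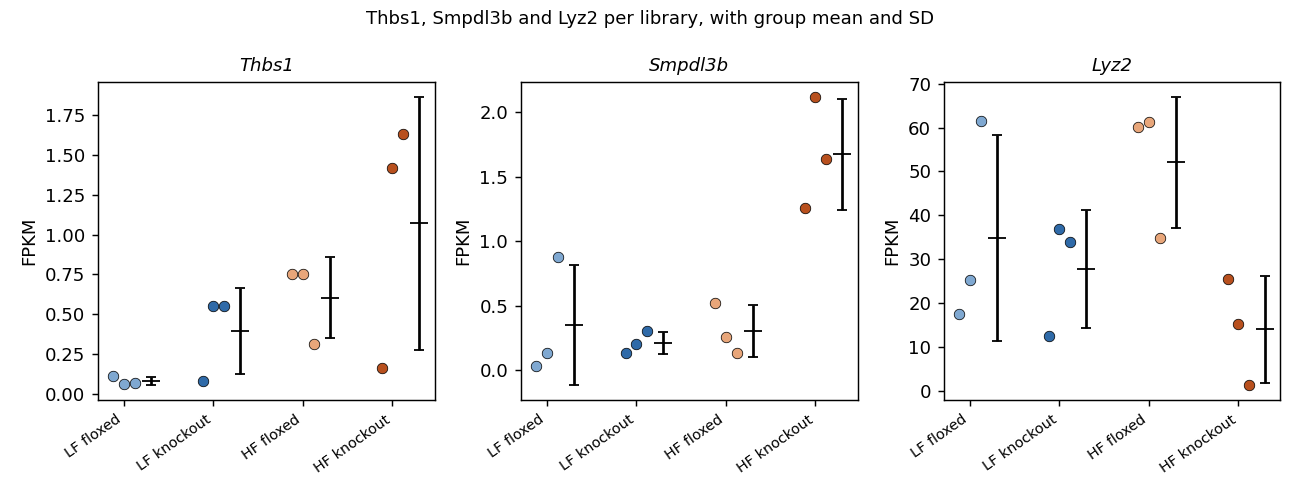
FPKM of Thbs1, Smpdl3b and Lyz2 (y axes, linear) in the 4 groups (x axes); points are single libraries, and the bars to their right are the group mean and SD of 3 libraries. Smpdl3b lay between 1.26 and 2.12 FPKM in HF knockout, above the other 9 libraries, while Thbs1 averaged 1.07 FPKM in HF knockout and 0.603 FPKM in HF floxed.

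The HF diet was compared with the LF diet in floxed mice to ask how the liver transcriptome responds when TSP1 is intact. Genes of extracellular matrix and hepatic stellate cells, the collagen-producing cells of liver, rose together: 22 of 22 tested members were higher on HF, with a median log2 change of 1.48 (camera adjusted p = 1e-12; adjusted p = 0.307 with an estimated correlation). Mmp2, a gelatinase, was 3.14-fold higher (log2 SE 0.4), at 2.53 ± 1.08 FPKM against 0.653 ± 0.0833, and Lox, a collagen cross-linking enzyme, was 9.99-fold higher (log2 SE 0.82). Lists of MHC class II genes (7 of 7 higher, median 1.70), interferon response genes (19 of 20, median 1.31) and lipid droplet and fatty acid uptake genes (13 of 14, median 1.77) rose as well. Camera adjusted p were 1.83e-09, 3.5e-09 and 1.38e-07, and with an estimated correlation the adjusted p were 0.275, 0.307 and 0.275. Cd36, a fatty acid translocase that also binds TSP1, averaged 50.7 ± 22.9 FPKM against 2.94 ± 1.04, a 14.1-fold difference. Cidea, a lipid droplet protein, held 27.37 to 68.17 FPKM in the HF floxed libraries and at most 0.11 FPKM in the LF floxed ones.

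Markers of other liver cells moved in the same comparison. Monocyte and lipid-associated macrophage markers rose (13 of 16 members higher, median 1.40, camera adjusted p = 0.000182; adjusted p = 0.356 with an estimated correlation). Among them were Gpnmb at 3.85 ± 2.17 FPKM against 0.0667 ± 0.0451 and Cx3cr1, a chemokine receptor, at 1.87 ± 0.972 against 0.23 ± 0.231. Kupffer cell markers, those of resident liver macrophages, were not called (median 0.01, mean -0.05, camera adjusted p = 0.541; its median and mean differ in sign). Inflammatory genes rose (12 of 16 higher, median 0.76, camera adjusted p = 0.000588; adjusted p = 0.414 with an estimated correlation). The chemokine genes Cxcl9 and Ccl5 were 3.43-fold and 3.92-fold higher. Cell cycle genes rose too (14 of 15, median 1.63, camera adjusted p = 0.00268; adjusted p = 0.569 with an estimated correlation). Hepatocyte secreted proteins and enzymes fell (15 of 17 lower, median -0.52, camera adjusted p = 0.000758; adjusted p = 0.389 with an estimated correlation). So did lipogenesis genes (14 of 18 lower, median -0.59, camera adjusted p = 0.00586; adjusted p = 0.549 with an estimated correlation). Mlxipl, a carbohydrate-responsive transcription factor, was at 25.6 ± 7.37 FPKM against 49.2 ± 4.17. With 1 library left out, the median of inflammatory genes was up to 1.85 (without LF floxed replicate 3), that of hepatocyte genes ran from -0.79 to -0.32 and that of lipogenesis genes was up to -0.28. The lipogenesis call was lost without LF floxed replicate 2 (camera adjusted p = 0.0652) or HF floxed replicate 3 (0.126).

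In the same floxed comparison, 7 of 8 female-biased liver genes were higher and the list rose (median 1.72, camera adjusted p = 0.00245; adjusted p = 0.275 with an estimated correlation). Of the male-biased genes 13 of 14 were lower, and that list fell (median -0.76, camera adjusted p = 0.0041; adjusted p = 0.569 with an estimated correlation), with a median of -2.11 without HF floxed replicate 3 and -0.50 without HF floxed replicate 2. Cyp2b9, a female-biased cytochrome P450, averaged 42.2 ± 5.42 FPKM on HF against 0.497 ± 0.189 on LF, a 72.3-fold difference (log2 SE 0.82, edgeR adjusted p = 0.056). Its neighbour in the family Cyp2b13 had 0 counts in the LF floxed group and was at least 95.3-fold higher on HF against a floor of 3 counts over the group. The 2 genes share 91.2% of 1756 aligned transcript bases, so the split of reads between them is uncertain. Both are members of the female-biased and of the xenobiotic list, so the results of these 2 lists are not independent in any comparison. NRF2 targets, unfolded protein response genes, xenobiotic targets, fatty acid oxidation genes and the list of TSP1 partners rose with camera adjusted p of 0.0263, 0.0102, 0.0389, 0.0221 and 0.0205, and bile acid genes fell (0.0378). With an estimated correlation these adjusted p were 0.369, 0.307, 0.503, 0.576, 0.307 and 0.595. The list called TSP1 partners here and below holds TSP1, its receptors and its partners, so Thbs1 itself is a member. Its member Cd36 is also on the lipid droplet list. Single libraries decided some of these calls: without HF floxed replicate 3 the unfolded protein response and TSP1 partners had camera adjusted p of 0.138 and 0.0583, and without LF floxed replicate 2 NRF2 targets had 0.058. Without HF floxed replicate 1 fatty acid oxidation and bile acid genes had 0.0546 and 0.0858, and the bile acid call was also lost without LF floxed replicate 1 (0.102) or HF floxed replicate 2 (0.0954). The xenobiotic call was lost without any of LF floxed replicate 1, HF floxed replicate 3 and HF knockout replicates 1 and 2 (0.0631, 0.247, 0.0634 and 0.067). With log2(FPKM + 1), the calls of female-biased, cell cycle, xenobiotic, NRF2 and TSP1 partner genes were lost (camera adjusted p = 0.194, 0.126, 0.784, 0.0703 and 0.0703). In alternatives chosen after the data were seen, the bile acid call was lost with both near-identical pairs averaged (0.0895) and with the clock gene score as a covariate (0.325).

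In total, camera called 17 of 33 lists in floxed libraries (13 up, 4 down), 0 with an estimated correlation and 3 by fry, the test of a list's own direction. Adjusted over the list alone, 16 of 22 matrix, 7 of 7 MHC class II, 13 of 20 interferon and 9 of 14 lipid droplet genes passed, against 0 each over all genes. No single gene passed edgeR's quasi-likelihood test over all 12587 genes (smallest adjusted p = 0.056). At an unadjusted p under 0.05 there were 1532 genes, where 629 are expected by chance. DESeq2 called 254 genes and limma voom with sample weights 1510. The highest voom weights went to the near-identical libraries, with 3.61 and 3.43 for LF knockout replicates 2 and 3. HF floxed replicates 1 and 2 had weights of 1.8 and 2.74. The voom count thus leans on libraries that may not be separate animals. The values of the 2 groups did not overlap in 24% of genes, where chance gives 10% for independent libraries. With the near-identical pair averaged to 1 value it was 29.3%, where chance gives 20%. A fit of the 6 libraries compared, planned beforehand, called 82 genes. This number ranged from 3 to 852 as each library was left out (852 without HF floxed replicate 3). The smallest p after Cyp2b9 among the higher genes were those of Serpinh1, a collagen chaperone, at 12.8 ± 2.55 FPKM against 3.57 ± 0.701, and Lgals1, a galectin, at 211.0 ± 91.5 against 19 ± 4.88 (edgeR adjusted p = 0.122 for both). Morf4l1b, Zfp395 and Vegfa led the lower genes, with edgeR adjusted p of 0.056, 0.122 and 0.175.

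**Figure D2:**
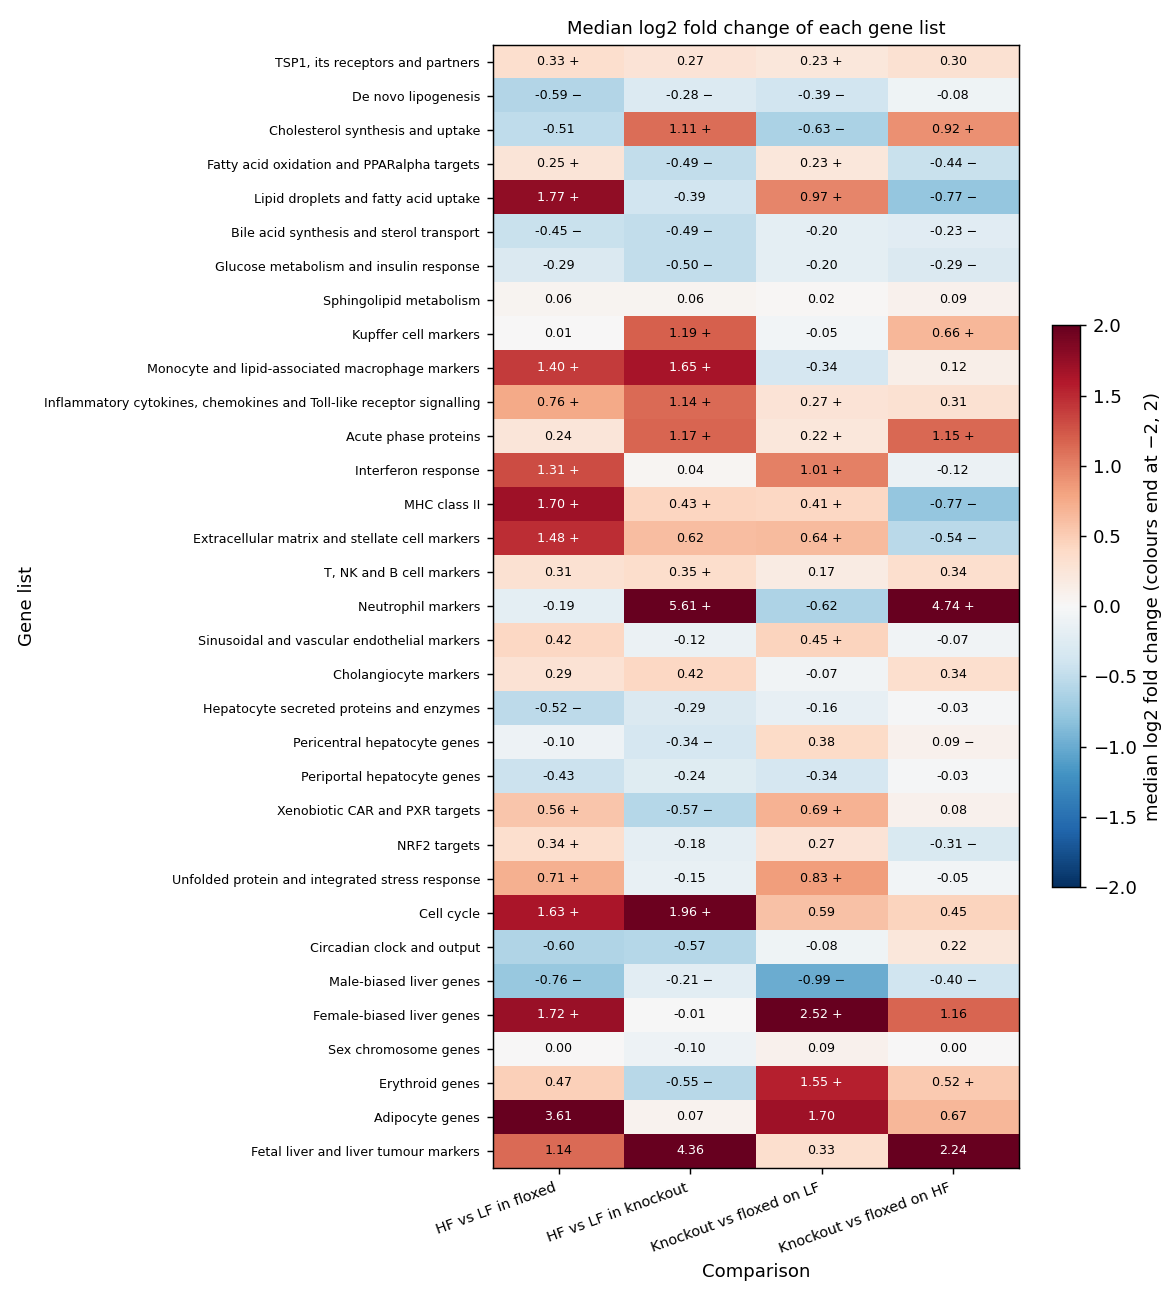
Median log2 fold change (colour and printed value) of the tested members of 33 gene lists (y axis) in 4 comparisons (x axis); + and − mark lists that camera called up or down at a preset correlation. In floxed libraries the matrix list (1.48), MHC class II (1.70) and lipid droplets (1.77) were higher on HF, and in HF knockout against HF floxed the same 3 lists had medians of -0.54, -0.77 and -0.77.

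**Figure D3:**
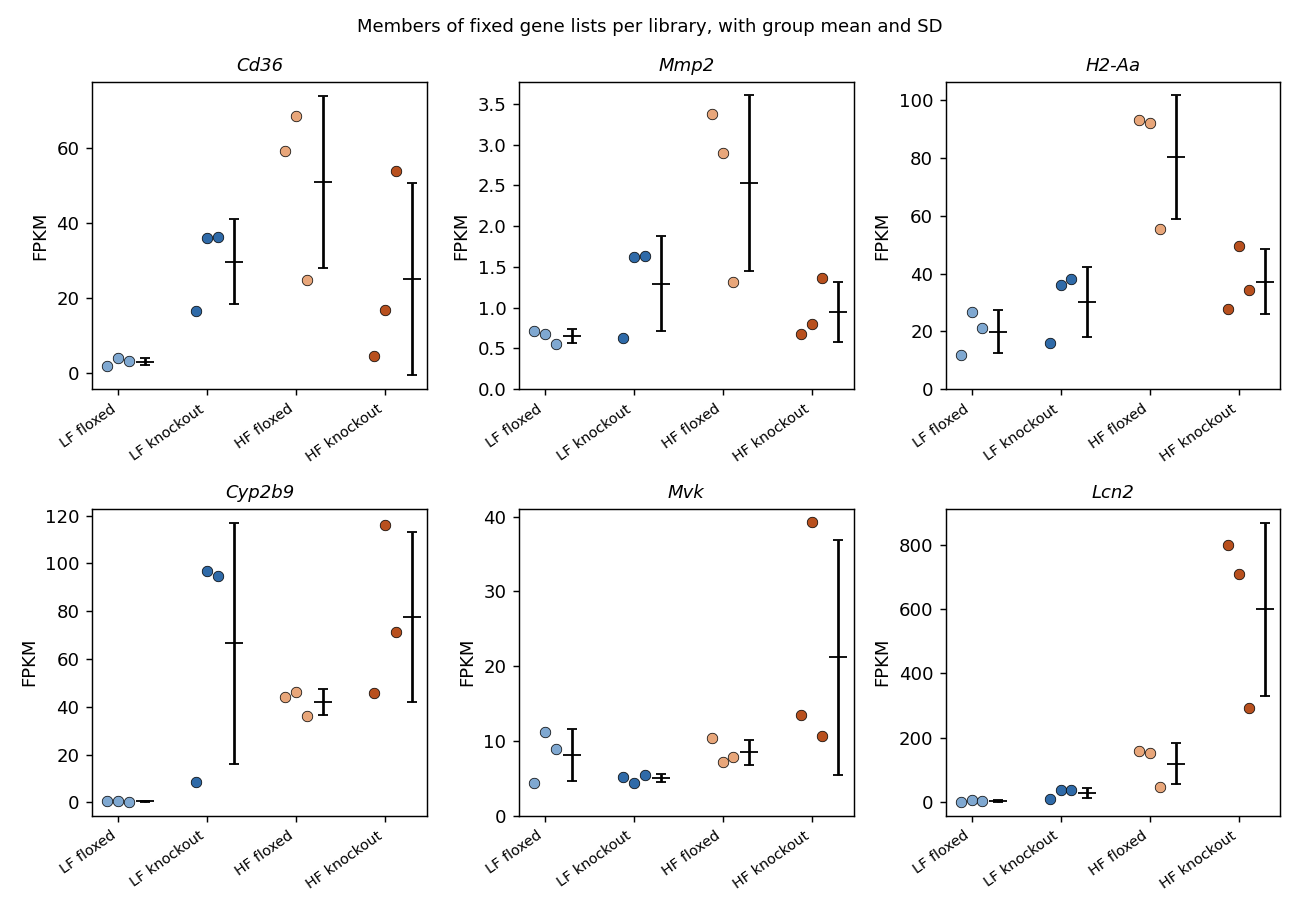
FPKM (y axes, linear) of 6 named list members in the 4 groups (x axes); points are single libraries, and the bars to their right are the group mean and SD of 3 libraries. Mmp2 averaged 2.53 FPKM in HF floxed and 0.947 FPKM in HF knockout, and Lcn2 averaged 119.0 and 599.0 FPKM in the same groups.

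In mice labelled knockout, the HF diet was compared with the LF diet in the same way. The lists of neutrophil markers (6 of 6 members higher, median 5.61), acute phase proteins (15 of 16, median 1.17), monocyte and lipid-associated macrophage markers (15 of 16, median 1.65) and inflammatory genes (16 of 16, median 1.14) rose. Camera adjusted p were 0.000138, 0.000138, 0.000111 and 0.000285, and with an estimated correlation the adjusted p were 0.458, 0.458, 0.458 and 0.486. Lcn2, an acute phase lipocalin, averaged 599.0 ± 269.0 FPKM on HF against 28.6 ± 15.6 on LF, a 22.8-fold difference (log2 SE 0.7, edgeR adjusted p = 0.26). Cholesterol synthesis genes rose (21 of 22 higher, median 1.11, camera adjusted p = 1.35e-05; adjusted p = 0.552 with an estimated correlation). With 1 library left out, the fatty acid oxidation median ran from -0.88 to -0.18, that of cholesterol genes was down to 0.26 and that of acute phase proteins down to 0.47. The size of the neutrophil change lay mostly in HF knockout replicate 3: without it the median was 1.39, with the list still called (camera adjusted p = 0.00492). The cholesterol call was lost without HF knockout replicate 2 (0.147), and that of acute phase proteins without HF knockout replicate 1 (0.229). Fatty acid oxidation genes fell (19 of 20 lower, median -0.49, camera adjusted p = 8.27e-06; adjusted p = 0.458 with an estimated correlation).

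Further lists called in libraries labelled knockout were Kupffer cell markers (12 of 13 higher), T, NK and B cell markers (11 of 14), cell cycle (14 of 15) and MHC class II (7 of 7), which rose with camera adjusted p of 0.0123, 0.0431, 0.00647 and 0.0383. The adjusted p with an estimated correlation were 0.559, 0.552, 0.559 and 0.552. Bile acid, male-biased, xenobiotic, glucose metabolism, pericentral, erythroid and lipogenesis genes fell, with camera adjusted p of 0.00039, 0.00168, 0.00261, 0.00354, 0.00391, 0.00391 and 0.0364 and adjusted p between 0.458 and 0.559 with an estimated correlation. Without HF knockout replicate 2, the calls of cell cycle, bile acid, male-biased, xenobiotic, glucose metabolism and pericentral genes were lost (camera adjusted p = 0.699, 0.286, 0.286, 0.0964, 0.0853 and 0.425), the pericentral list with its direction turned to up. Those of MHC class II and of T, NK and B cell markers were lost without it too (0.339 and 0.234), and without LF knockout replicate 1 (0.497 and 0.451) or HF knockout replicate 1 (0.0814 and 0.18). Those of Kupffer cell markers and lipogenesis were lost without LF knockout replicate 1 (0.0991 and 0.74), HF knockout replicate 1 (0.241 and 0.552) or HF knockout replicate 3 (0.478 and 0.0976). With log2(FPKM + 1) the lipogenesis call was lost (0.0768). Monocyte, inflammatory, MHC class II, cell cycle, lipogenesis, bile acid and male-biased lists were called in the same direction in floxed libraries, and fatty acid oxidation and xenobiotic lists in the opposite one. Of these 17 lists, 0 were called with an estimated correlation and 0 by fry. Adjusted over the list alone, 5 of 6 neutrophil markers, 8 of 16 acute phase proteins, 7 of 16 monocyte markers and 0 of 16 inflammatory genes passed, against 0 each over all genes. No gene passed over all genes (edgeR, smallest adjusted p = 0.203; 1534 genes at an unadjusted p under 0.05), DESeq2 called 126 and voom with weights 9, and 13.9% of genes had groups that did not overlap (18.7% with the near-identical LF knockout pair as 1 value, where chance gives 20%). Morf4l1b, Lcn2 and Pfkfb4 led the higher genes and Gnai1, Zfp574 and Acot4 the lower ones (edgeR adjusted p = 0.203, 0.26, 0.344, 0.344, 0.344 and 0.344), and Thbs1 differed by 1.4 on the log2 scale (SE 0.74, edgeR adjusted p = 0.47).

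Across the 12587 genes, the diet effects in floxed and in knockout libraries correlated weakly (Pearson r = 0.191, Spearman rho = 0.175; genes are not independent replicates). Of the genes at an unadjusted p under 0.05 in both, 167 had the same sign and 64 the opposite sign; 121 were higher in both, where independent lists would share 75.9, and 46 lower in both, where they would share 22.6. The correlation rested on HF knockout replicate 2, since without it r was -0.009.

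The comparison of genotypes on the HF diet addresses the study's main question. In the libraries labelled knockout MHC class II fell (7 of 7 lower, median -0.77), as did lipid droplets and fatty acid uptake (12 of 14 lower, median -0.77) and matrix and stellate cell markers (18 of 22 lower, median -0.54). Camera adjusted p were 0.000106, 0.000125 and 3.31e-05, and with an estimated correlation the adjusted p were 0.523, 0.523 and 0.689. H2-Aa, an MHC class II chain, averaged 37.2 ± 11.2 FPKM against 80.3 ± 21.4, Mmp2 averaged 0.947 ± 0.363 against 2.53 ± 1.08, and Lum, a matrix proteoglycan, averaged 2.18 ± 0.919 against 7.8 ± 3.04. Without HF knockout replicate 1, in which Cidea was at 0 FPKM, the lipid droplet and matrix calls were lost (camera adjusted p = 0.0653 and 0.285). With 1 library left out, the MHC class II median was down to -1.19, the lipid droplet median ran from -1.53 to -0.45 and the matrix median from -0.89 to -0.11. In the 8 libraries with low Dbp, an alternative chosen after the data were seen, these calls (0.0515 and 0.308) and those of acute phase, Kupffer and NRF2 genes (0.308, 0.413 and 0.392) were lost. MHC class II, lipid droplet and matrix lists had risen with HF in floxed mice, but both comparisons use the HF floxed libraries with opposite sign, so opposite directions can arise without a change, and no value without a change was simulated for lists. Interferon and monocyte markers, which had risen too, were not called here (camera adjusted p = 0.167 and 0.947).

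Other lists were higher on HF in the libraries labelled knockout. Acute phase proteins rose (15 of 16 higher, median 1.15, camera adjusted p = 5.33e-06; adjusted p = 0.523 with an estimated correlation). Itih4 stood at 1080.0 ± 109.0 FPKM against 515.0 ± 36.1, and Lcn2 was 5.94-fold higher. This call was lost without HF knockout replicate 1 (median 0.33, camera adjusted p = 0.223), where Saa1 stood at 3482.61 FPKM. Neutrophil markers rose (6 of 6 higher, median 4.74, camera adjusted p = 3.31e-05; adjusted p = 0.523 with an estimated correlation). Much of their size lay in HF knockout replicate 3, where S100a8, a neutrophil alarmin, stood at 176.38 FPKM against 2.55 and 0.93 in the other HF knockout libraries. Without that library the median was 0.97 and the list was still called (camera adjusted p = 0.00807). Cholesterol synthesis genes rose (22 of 22 higher, median 0.92, camera adjusted p = 5.33e-06; adjusted p = 0.689 with an estimated correlation). This call was lost without HF knockout replicate 2 (median 0.14, camera adjusted p = 0.307), in which Sqle, squalene epoxidase, stood at 90.29 FPKM against 12.85 and 9.47. Kupffer cell markers (12 of 13 higher, median 0.66) and erythroid genes (4 of 5, median 0.52) rose with camera adjusted p of 0.0228 and 0.0181 and adjusted p of 0.754 and 0.614 with an estimated correlation. The Kupffer median ran from 0.38 to 1.04 with 1 library left out. The Kupffer call was lost without HF floxed replicate 3 (0.281), HF knockout replicate 1 (0.344) or HF knockout replicate 3 (0.747), and the erythroid call without HF floxed replicate 2 (0.0586), HF knockout replicate 1 (0.0664) or HF knockout replicate 3 (0.223).

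Fatty acid oxidation genes fell on HF in the libraries labelled knockout (18 of 20 lower, median -0.44, camera adjusted p = 4.41e-06; adjusted p = 0.523 with an estimated correlation). The median was -0.11 without HF knockout replicate 2, with the list still called (camera adjusted p = 0.0162), and -0.86 without HF knockout replicate 3. Acaa1b, a peroxisomal thiolase, stood at 339.0 ± 340.0 FPKM against 992.0 ± 311.0. Glucose metabolism genes fell (8 of 12 lower, median -0.29), among them the glycolytic enzyme Pklr at 58.6 ± 21.4 against 144.0 ± 46.5 FPKM. NRF2 targets (median -0.31), bile acid genes (median -0.23) and male-biased genes (median -0.40) fell too, and the pericentral list was called down although its median was 0.09 and its mean -0.05. For these 5 lists in order, camera adjusted p were 0.0149, 0.0276, 0.0168, 0.0146 and 0.0231, and with an estimated correlation 0.523, 0.523, 0.754, 0.754 and 0.754. With 1 library left out, the medians of glucose, NRF2, bile acid, male-biased and pericentral lists were up to -0.14, -0.12, 0.15, 0.62 and 0.61, and those of all but NRF2 down to -0.79, -0.83, -1.84 and -0.81. Without HF knockout replicate 2 the pericentral list was called up instead (camera adjusted p = 0.00744), and the glucose, bile acid and male-biased calls were lost (0.141, 0.568 and 0.844), the bile acid list with its direction turned to up. Without HF floxed replicate 3 the bile acid, male-biased and pericentral calls were lost (0.343, 0.733 and 0.307). The male-biased call was also lost without HF knockout replicate 3 (0.0681), and the NRF2 call without any of HF floxed replicates 1 and 2, HF knockout replicate 1 and LF knockout replicates 1 and 3 (0.0684, 0.114, 0.344, 0.0518 and 0.052). With log2(FPKM + 1) the bile acid, male-biased and pericentral calls were lost (0.0507, 0.06 and 0.16). Cyp4a12b, a male-specific cytochrome P450, averaged 0.957 ± 1.13 FPKM against 17 ± 16.2, and Mup20, a major urinary protein, averaged 2520.0 ± 764.0 against 9490.0 ± 1600.0.

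For the genotypes on HF, camera called 14 of 33 lists (5 up, 9 down), 0 with an estimated correlation and 0 by fry. Adjusted over the list alone, 5 of 6 neutrophil markers, 5 of 16 acute phase proteins, 3 of 5 fetal and tumour markers, 2 of 7 MHC class II genes, 2 of 14 male-biased genes and 1 of 22 matrix genes passed, against 0 each over all genes. The fetal and tumour markers that passed, Afp, Gpc3 and Cd24a, rest largely on HF knockout replicate 2, with Gpc3 at 245.57 CPM there against 0 and 0.13 in the other HF knockout libraries. No gene passed over all genes (edgeR, smallest adjusted p = 0.157; 963 genes at an unadjusted p under 0.05), DESeq2 called 69 and voom with weights 0, and 10.1% of genes had groups that did not overlap (14.4% with the near-identical HF floxed pair as 1 value, where chance gives 20%). The genes of smallest p were Morf4l1b, Zfp362 and Cxcl1, a neutrophil chemokine, among the higher (edgeR adjusted p = 0.157, 0.252 and 0.457) and Gnai1, Lum and Mapt among the lower (edgeR adjusted p = 0.157, 0.457 and 0.457). Sphingolipid genes, the list that holds Smpdl3b, were not called (13 of 23 higher, median 0.09, mean -0.05, camera adjusted p = 0.542).

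On the LF diet, the libraries labelled knockout were compared with the floxed ones. The same 3 LF floxed libraries are subtracted here and in the comparison of diets in floxed mice, so lists can move alike in both without a change. Female-biased genes rose as a list (8 of 8 members higher, median 2.52, camera adjusted p = 3.17e-08), the only list of any comparison called with an estimated correlation (adjusted p = 0.0441); fry called it too (adjusted p = 0.00902). Cyp2b9 rose 127-fold, from 0.497 ± 0.189 to 66.6 ± 50.4 FPKM (log2 6.98, SE 0.85, edgeR adjusted p = 0.0362), and Cyp2b13, with 0 counts in LF floxed, was at least 234-fold higher against a floor of 3 counts over the group. In LF knockout, Cyp2b9 stood at 96.87 and 94.5 FPKM in replicates 2 and 3, which were nearly identical to each other, and at 8.47 in replicate 1. Cyp2b13 stood at 13.39 and 13.92 FPKM in replicates 2 and 3 and at 0.19 in replicate 1, so its bound rests mostly on the near-identical pair. Erythroid genes rose as a list (5 of 5 members higher, median 1.55, camera adjusted p = 2.58e-10; adjusted p = 0.0665 with an estimated correlation, fry adjusted p = 0.00902), with the globin gene Hbb-bs at 519.0 ± 127.0 FPKM against 160.0 ± 9.98.

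Interferon genes (18 of 20 higher, median 1.01), xenobiotic targets (14 of 14, median 0.69), unfolded protein response genes (10 of 14, median 0.83) and lipid droplet genes (11 of 14, median 0.97) also rose on LF, with camera adjusted p of 3.17e-08, 4.78e-06, 1.28e-05 and 2.31e-05 and adjusted p of 0.313, 0.163, 0.0883 and 0.313 with an estimated correlation. Cd36 averaged 29.5 ± 11.4 FPKM against 2.94 ± 1.04, and Vnn1, a pantetheinase and PPARalpha target, 48.8 ± 12 against 6.97 ± 4.77. In LF knockout, Cidea stood at 47.22 and 52.43 FPKM in the near-identical replicates 2 and 3 and at 0.61 FPKM in replicate 1. Matrix, fatty acid oxidation, endothelial, MHC class II, acute phase, inflammatory and TSP1 partner genes rose with camera adjusted p from 0.00041 to 0.0351, and cholesterol synthesis, male-biased and lipogenesis genes fell with 0.00248, 0.00507 and 0.012. With an estimated correlation these adjusted p were 0.666, except 0.313 for TSP1 partners. Without LF floxed replicate 2 the cholesterol and endothelial calls were lost (camera adjusted p = 0.404 each). Lost without LF knockout replicate 1 were those of fatty acid oxidation, male-biased and acute phase genes (0.0603, 0.0795 and 0.139), and without LF floxed replicate 1 those of male-biased, acute phase and MHC class II genes (0.178, 0.389 and 0.626). MHC class II was also lost without LF knockout replicate 2 (0.137) or 3 (0.167). Lipogenesis, inflammatory genes and TSP1 partners were lost without LF floxed replicate 1 (0.0618, 0.658 and 0.161), LF floxed replicate 2 (0.225, 0.225 and 0.0969), LF knockout replicate 2 (0.137, 0.137 and 0.0578) or LF knockout replicate 3 (0.167, 0.082 and 0.0582), and inflammatory genes also without HF knockout replicate 2 (0.0523). With log2(FPKM + 1) the calls of matrix, endothelial, MHC class II, acute phase, inflammatory and TSP1 partner genes were lost (0.0812, 0.0935, 0.136, 0.0686, 0.316 and 0.0935). Leaving out 1 library of the near-identical LF knockout pair keeps the other. With this pair averaged, 4 of the 16 called lists were lost: lipogenesis, MHC class II, inflammatory and TSP1 partner genes (camera adjusted p = 0.133, 0.134, 0.0919 and 0.0549). In all, 16 of 33 lists were called (13 up, 3 down), 1 with an estimated correlation and 2 by fry. Adjusted over the list alone, 7 of 20 interferon, 6 of 14 lipid droplet, 4 of 5 erythroid and 3 of 8 female-biased genes passed.

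Besides Cyp2b9, the gene called on LF over all genes was Morf4l1b, which fell (log2 -1.68, SE 0.21, edgeR adjusted p = 0.0362), from 13 ± 2.44 to 4.56 ± 0.581 FPKM. It is named as a copy of Morf4l1, and the summed counts of both genes were 191.9 ± 8.1 CPM in LF floxed and 177.5 ± 14.1 in LF knockout, so its value is uncertain where reads are shared. These 2 genes were called of 12587 (646 at an unadjusted p under 0.05, where 629 are expected by chance). Both calls were lost when LF knockout replicates 2 and 3 were averaged to 1 library (edgeR adjusted p = 0.161 for Cyp2b9 and 0.343 for Morf4l1b). The log2 differences hardly moved, to 6.62 (SE 0.86) and -1.63 (SE 0.25), in a fit with fewer libraries. The Cyp2b9 call was also lost without any 1 of LF floxed replicates 1, 2 and 3 (0.203, 0.184 and 0.248), LF knockout replicates 2 and 3 (0.154 and 0.162) and HF floxed replicates 1, 2 and 3 (0.0697, 0.102 and 0.0613). That of Morf4l1b was lost without the same libraries (0.203, 0.118, 0.248, 0.358, 0.385, 0.0697, 0.102 and 0.0613) and without HF knockout replicate 1 (0.0508). Over all alternatives the adjusted p ran from 1.92e-23 (DESeq2) to 0.474 for Cyp2b9 and from 9.85e-09 (DESeq2) to 0.695 for Morf4l1b. DESeq2 called 34 and voom with weights 832, and 13.4% of genes had groups that did not overlap (17% with the near-identical LF knockout pair as 1 value, where chance gives 20%). Voom weighted LF knockout replicates 2 and 3 by 3.61 and 3.43 and replicate 1 by 0.47, so its count leans on the near-identical pair. Hbb-bt, Hbb-bs and Sgk1, a serum-induced kinase, followed with edgeR adjusted p of 0.0592 each, then Mum1 with 0.386, and Thbs1 differed by 2.19 (log2, SE 0.84, edgeR adjusted p = 0.929).

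Averaged over both diets, the difference between genotypes passed for no gene (edgeR, smallest adjusted p = 0.0776 for Cyp2b9 and Hbb-bt), with 23 called by DESeq2 and 4 by voom with weights. At an unadjusted p under 0.05 there were 405 genes, fewer than the 629 expected by chance. The values of the 2 genotypes did not overlap in 0.1% of genes, where chance gives 0.22% for independent libraries. Camera called 16 of 33 lists (12 up, 4 down), 0 with an estimated correlation and 2 by fry. Erythroid (4 of 5 higher, median 1.07), acute phase (16 of 16, median 0.60) and female-biased genes (8 of 8, median 1.71) rose with camera adjusted p of 1.5e-10, 4.65e-08 and 2.63e-07, and male-biased genes fell (13 of 14 lower, median -0.70, camera adjusted p = 2.7e-05). With an estimated correlation the adjusted p were 0.0625, 0.248, 0.0625 and 0.6. The male-biased median was -0.14 without HF floxed replicate 3 and -1.36 without HF knockout replicate 1. Sphingolipid genes, not called on either diet alone, were called up (14 of 23 higher, median 0.12, camera adjusted p = 0.0486; adjusted p = 0.244 with an estimated correlation), a call that held in 1 of 12 fits with 1 library left out (0.0518 to 0.341 in the others). Calls of bile acid, cell cycle, lipogenesis, glucose metabolism, inflammatory, interferon, Kupffer, T, NK and B cell and TSP1 partner genes were each lost without at least 1 library. Adjusted over the list alone, 5 of 16 acute phase, 4 of 5 erythroid and 4 of 8 female-biased genes passed. Hbb-bs and Sgk1 had edgeR adjusted p of 0.109, Cyp4a12b 0.593 and Mup20 0.717, and the log2 difference of Thbs1 was 1.57 (SE 0.55, edgeR adjusted p = 0.994).

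The interaction of diet and genotype tests whether the diet effect differed between genotypes. Fatty acid oxidation genes (20 of 20 members), interferon genes (20 of 20), matrix genes (21 of 22) and lipid droplet genes (12 of 14) had a lower diet effect in the libraries labelled knockout, and cholesterol synthesis genes a higher one (22 of 22). Their median differences were -0.91, -1.17, -1.28, -1.43 and 1.53 on the log2 scale. With 1 library left out they ran from -1.43 to -0.60, -1.55 to -0.89, -1.73 to -0.96, -2.12 to -1.26 and 0.76 to 2.03, and the lowest cholesterol value was that without HF knockout replicate 2. Camera adjusted p were 3.5e-07, 8.91e-06, 6.54e-07, 1.23e-06 and 9.46e-07, and with an estimated correlation the adjusted p were 0.362, 0.427, 0.427, 0.356 and 0.506. Camera called 14 of 33 lists (2 up, 12 down), 0 with an estimated correlation and 0 by fry. Adjusted over the list alone, 6 of 14 lipid droplet, 4 of 7 MHC class II, 4 of 6 neutrophil, 4 of 5 erythroid and 4 of 14 xenobiotic genes passed.

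Over all genes 2 passed the interaction test, with 1202 at an unadjusted p under 0.05, 107 called by DESeq2 and 34 by voom with weights. Gnai1, an inhibitory G protein subunit, averaged 0.217 ± 0.0666 FPKM in LF floxed, 0.997 ± 0.429 in LF knockout, 2.32 ± 0.557 in HF floxed and 0.103 ± 0.0777 in HF knockout, an interaction of -6.26 (log2, SE 0.79, edgeR adjusted p = 0.0358) that was no longer called when LF knockout replicates 2 and 3 were averaged (-6.08, SE 0.84, adjusted p = 0.148). Morf4l1b averaged 13 ± 2.44, 4.56 ± 0.581, 5.09 ± 0.494 and 12.8 ± 3.12 FPKM in the same order (interaction 3.11, SE 0.3, edgeR adjusted p = 0.00452), and when the near-identical libraries of LF knockout and HF floxed were averaged to 1 each, its interaction was 2.98 (SE 0.36, adjusted p = 0.163). The summed counts of Morf4l1b and Morf4l1 were 191.9 ± 8.1, 177.5 ± 14.1, 170.3 ± 6.2 and 162.0 ± 16.6 CPM in that order of groups. The split of reads between the 2 genes is uncertain, and so is this interaction. Mum1, Zfp362, Cyp2b9 and Gdf15, a stress-induced cytokine, followed with an edgeR adjusted p of 0.241 each, and Thbs1 had -1.24 (SE 1.09, edgeR adjusted p = 0.737).

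Genes changed by HF in floxed mice were compared with genes changed the opposite way by the knockout on HF. No gene was called in both comparisons (edgeR), and at an unadjusted p under 0.05 in both, 257 genes had opposite signs and 11 the same sign. Of these, 139 were higher with HF and lower in the knockout, where independent lists would share 26.4, and 118 the reverse, where they would share 30.8. Both comparisons use the HF floxed libraries with opposite sign, and unchanged groups simulated with the same sharing gave 132 opposite genes on average (117 to 153 in 20 draws). The correlation of the fold changes was -0.286, against -0.499 in the simulation, and their covariance was -0.142 against -0.121 (SD 0.0058). The 3 HF floxed libraries are too few to be split, so part of the excess may come from the shared libraries.

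Libraries within a group differed in ways that diet and genotype do not name. Dbp, a clock output gene, stood at 90.82, 57.85, 84.17 and 34.14 FPKM in LF floxed replicates 2 and 3, LF knockout replicate 1 and HF knockout replicate 1, and between 1.98 and 5.03 FPKM in the other 8, which include all HF floxed libraries. HF knockout replicate 2 held 101.49 FPKM of Gpc3, a fetal liver proteoglycan, against at most 0.89 in the others, and 10.97 FPKM of Glul, the glutamine synthetase of pericentral hepatocytes, against at least 252.97. The clock list holds genes of opposite phase, such as Dbp and Arntl, whose changes can cancel in a test of 1 direction. That test therefore cannot decide whether clock genes differ. Clock genes as a list were not called in any comparison (camera adjusted p = 0.102, 0.0647, 0.947 and 0.814 for HF in floxed, HF in knockout, knockout on HF and knockout on LF). Nor were fetal and tumour markers called (camera adjusted p = 0.0968, 0.0525, 0.409 and 0.473 in the same order), or periportal, cholangiocyte, adipocyte and sex chromosome genes, whose smallest camera adjusted p in these 4 comparisons were 0.145, 0.127, 0.324 and 0.673.

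**Figure D4:**
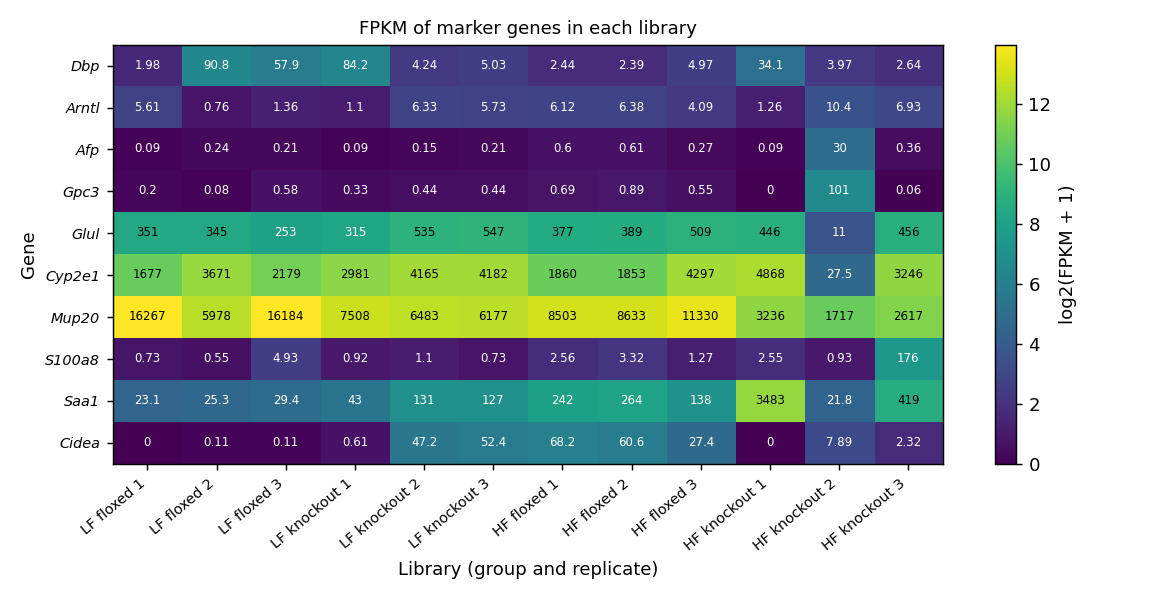
FPKM (printed) and log2(FPKM + 1) (colour) of 10 marker genes (y axis) in the 12 libraries (x axis). Dbp is between 34.1 and 90.8 FPKM in 4 libraries of 3 groups and at most 5.03 FPKM in the other 8, and HF knockout replicate 2 has the highest Gpc3 (101.49 FPKM) and the lowest Glul (10.97 FPKM).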

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

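The interaction tests in this part were planned before the data were examined, and the look at loci without a gene name was chosen only after the values were seen. The diet effect differed between genotypes, by the test of the difference itself, for Morf4l1b (log2 interaction 3.11, edgeR adjusted p = 0.00452) and Gnai1 (-6.26, edgeR adjusted p = 0.0358). Morf4l1b stood at 13 ± 2.44 and 12.8 ± 3.12 FPKM in LF floxed and HF knockout and at 4.56 ± 0.581 and 5.09 ± 0.494 in LF knockout and HF floxed (SD of 3 libraries). It is named as a copy of Morf4l1, so these values are uncertain where reads are shared between the copies. Of 60 drawn splits of the libraries within the design, only the real one gave 2 genes and the highest other gave 1. This share is under the 5% set beforehand for 1 comparison, without allowance for the 6 comparisons tested in this way. The test therefore does not exclude chance. It also takes the libraries as independent, which the near-identical pairs put in doubt. Averaging near-identical libraries ended both calls: with both pairs averaged to 1 library each, the adjusted p was 0.163 for Morf4l1b (1.87e-16 to 0.176 over its alternatives) and 0.677 for Gnai1 (2.3e-12 to 0.884). The interactions themselves hardly moved, from 3.11 (SE 0.3) to 2.98 (SE 0.36) and from -6.26 (SE 0.79) to -6.02 (SE 0.94), in a fit with fewer libraries. The Gnai1 call was also lost without any of LF floxed replicates 1, 2 and 3 (0.156, 0.125 and 0.177), LF knockout replicates 2 and 3 (0.151 and 0.152), HF floxed replicates 1, 2 and 3 (0.179, 0.171 and 0.0595) and HF knockout replicate 2 (0.0856). That of Morf4l1b held with each library left out (at most 0.0388).

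Gene lists whose diet effect was lower in the libraries labelled knockout were fatty acid oxidation (camera adjusted p = 3.5e-07, 20 of 20 members lower), matrix and stellate cell markers (6.54e-07, 21 of 22), lipid droplets (1.23e-06, 12 of 14), interferon response (8.91e-06, 20 of 20), xenobiotic targets (2.64e-05, 11 of 14), MHC class II (8.04e-05, 7 of 7), erythroid genes (0.000452, 5 of 5), female-biased genes (0.000814, 6 of 8), unfolded protein response (0.00374, 9 of 14), NRF2 targets (0.00915, 9 of 10), endothelial markers (0.0216, 10 of 12) and pericentral genes (0.0343, 8 of 11). Lists with a higher diet effect were cholesterol synthesis (9.46e-07, 22 of 22) and neutrophil markers (0.00117, 6 of 6). With an estimated correlation none of these 14 passed, with adjusted p from 0.356 to 0.866, and fry called 0.

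Single libraries decided some of these list results. Without HF knockout replicate 3 the unfolded protein response had a camera adjusted p of 0.173, and without LF floxed replicate 2 or HF knockout replicate 1 NRF2 targets had 0.0528 and 0.0668 and endothelial markers 0.227 and 0.786. The pericentral result was lost without LF floxed replicates 1 or 3, LF knockout replicates 2 or 3, HF floxed replicate 3 or HF knockout replicate 2 (0.0597, 0.0882, 0.0517, 0.0587, 0.185 and 0.458, the last with the opposite sign). With log2(FPKM + 1) the female-biased, endothelial and pericentral results were lost (0.375, 0.277 and 0.32).

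For the other counts of genes, the real value and the highest other split were 0 and 0 for HF against LF in floxed libraries (10 of 10 splits as high), 0 and 3 for HF against LF in knockout libraries (10 of 10), 0 and 20 for the genotype on HF (10 of 10) and 2 and 1 for the genotype on LF (1 of 10). These 10 splits are too few for a share under 0.05, and a real count of 0 is reached by every split, so it tests nothing. The split with 20 genes set HF floxed replicates 1 and 2 with HF knockout replicate 2, which points to a structure of the samples other than genotype. For the genotype averaged over diets the real count was 0 as well, reached by 60 of 60 splits whatever the samples, with 1 as the highest other.

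Outside the genes tested, 1 locus without a gene name, 15226 bases long and mitochondrial by its annotation in the files, took 5.3 to 16.06% of the estimated counts of a library (856642 to 2590554 counts). There is no control sample for this signal.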

How the results depend on the processing

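The averaging of pairs, the clock score, the 8 libraries with low Dbp, the kept loci without a gene name and the alternatives of the 6-library fits were chosen only after the results were seen; the cause of the changes below was not tested. For HF against LF in floxed libraries, edgeR's 0 genes became 254 with DESeq2, 1 with log2(FPKM + 0.1), 1 without a filter, 82 with the compared groups only, 1510 with voom weights, 158 without HF floxed replicate 3 and HF knockout replicate 1, 6 in the 8 libraries with low Dbp, 3 with loci without a gene name kept, and 0 to 14 with each library left out (14 without HF floxed replicate 3, 7 without LF knockout replicate 1 or HF knockout replicate 1). The 82 genes became 4 with the pair averaged, 3 with the clock score, 4 with the replicate block and 3 to 852 with each library left out. For HF in knockout libraries, 0 became 126 with DESeq2, 9 with voom weights, 1 with the clock score, 2 without the 2 libraries with another form of file name, and 0 to 10 with each left out (10 without HF knockout replicate 3, 1 without replicate 1). For the genotype on HF, 0 became 69 with DESeq2, 3 without those 2 libraries, and 0 to 14 (14 without HF knockout replicate 3, 2 without replicate 1). For the genotype on LF, 2 became 34 with DESeq2, 0 with log2(FPKM + 1), 1 with log2(FPKM + 0.1), 11 with the compared groups only, 0 with the replicate block, 832 with voom weights, 0 with a minimum change of 1.5-fold, 7 without those 2 libraries, 0 with 1 near-identical pair averaged, 0 with both near-identical pairs averaged, 4 in the 8 libraries with low Dbp, 0 with both pairs averaged and HF knockout replicate 2 left out, and 0 to 13 with each left out (13 without LF knockout replicate 1, 4 and 5 without HF knockout replicates 2 and 3, 0 without any other library of LF or of HF floxed). The 11 genes became 0 with the pair averaged, 45 with the clock score, 3 with the replicate block and 0 to 147 with each left out (147 without LF knockout replicate 1). Averaged over diets, 0 became 23 with DESeq2, 1 without a filter, 4 with voom weights, 2 with the clock score, 3 with low Dbp, 1 without those 2 libraries, and 0 to 8 (8 without LF knockout replicate 1, 2 without HF knockout replicate 3). For the interaction, 2 became 107 with DESeq2, 1 with the replicate block, 34 with voom weights, 5 without those 2 libraries, 1 with 1 pair averaged, 0 with both pairs averaged, 7 with low Dbp, 0 with both pairs averaged and HF knockout replicate 2 left out, 1 with loci without a gene name kept, and 1 to 17 (17 without HF knockout replicate 3, 10 without LF knockout replicate 1, 1 without any other except HF knockout replicate 1). Replicate numbers did not pair the samples: the correlation of libraries with the same number had a median of -0.04 and passed 0.1 in 4 of 18 pairs.

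Smpdl3b between diets in floxed libraries (log2 -0.47) reversed to 0.27 with log2(FPKM + 0.1), 0.57 with voom weights and 2.75 with low Dbp, and ran from -1.07 to 1.54 with each library left out (1.54 without LF floxed replicate 3); between genotypes on HF it ran from 2.27 to 3.18. Thbs1 ran from 2.44 to 2.94 between diets in floxed libraries and from 0.59 to 1.46 between genotypes on HF. Lyz2 between diets in floxed libraries ran from -0.01 (without LF floxed replicate 1, reversed from 0.3) to 0.97 (without LF floxed replicate 3). Axin2, a pericentral gene, ran between genotypes on HF from -1.02 to 0.06 (-0.49 with all libraries, reversed without HF knockout replicate 2) and was 0.12 when both pairs were averaged as well. The correlation of diet effects reversed from 0.191 to -0.009 without HF knockout replicate 2, and the 0 genes changed in opposite ways became 257 at an unadjusted p under 0.05. Lists past 5%, in the order HF in floxed, HF in knockout, genotype on HF, genotype on LF, averaged and interaction, numbered 17, 17, 14, 16, 16 and 14; with an estimated correlation 0, 0, 0, 1, 0 and 0; with fry 3, 0, 0, 2, 2 and 0; and with each library left out 15 to 23, 9 to 21, 9 to 15, 10 to 22, 11 to 19 and 12 to 19. Of the called lists, in the same order, 5, 1, 3, 6, 2 and 3 were lost with log2(FPKM + 1), where neutrophil markers had too few members to be tested. With both pairs averaged 1, 0, 1, 4, 1 and 0 were lost, with the clock score 1, 3, 1, 0, 2 and 1, and with low Dbp 1, 5, 5, 3, 2 and 2 (lipogenesis with HF in knockout, and endothelial markers in the interaction, with the opposite sign). HF in knockout gave 8 lists with both pairs averaged and HF knockout replicate 2 left out, and the genotype on LF gave 10 lists with log2(FPKM + 1).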

Other observations

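The tests of depth, highest shares, list shifts, fetal markers, clock score range, pair noise, pair gap and Lyz2 in this part were chosen only after the result was seen; those on abundant genes, clock genes left out of the score and pair variation were written before it.

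Libraries of the HF knockout group differed in the genes that carry its mean. Replicate 1 held 3482.61 FPKM of Saa1, a serum amyloid, against 21.83 and 419.14 in replicates 2 and 3. Replicate 3 held 187.42 FPKM of S100a9, a neutrophil protein, with 35.25 FPKM of Csf1r, the macrophage growth factor receptor, and 1.35 FPKM of Lyz2. Replicate 2 held 743.15 FPKM of Spp1, osteopontin, against 23.54 and 46.19, with Cyp2e1, a pericentral cytochrome P450, at 27.51 FPKM against at least 1677.24 in the other 11 libraries. Mup7, a major urinary protein, ranged from 2.24 to 19968.51 FPKM within HF knockout alone, which is also its range over the 12 libraries.

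HF knockout replicate 2 stood apart from the other 11 libraries, with a highest correlation to any of them of 0.89 where the lowest of the others was 0.917. Its total of 15080382 rounded counts, against 13336960 to 14598536, excludes low depth. The 50 most abundant genes took 45.7% of its counts, against 31.5 to 39.4% in the others, which can lower all other genes alike by a log2 shift of at most -0.34. Outside these genes, 7 of the 33 lists lay above 0 against the other 11 libraries by more than 2 SE, such as cell cycle with a median of 2.73. Below that shift lay 6 lists, such as pericentral genes with -3.94, so a few genes taking most counts are excluded as the cause of these moves. Other tests of it decided nothing: without the 50 genes its highest correlation was 0.888 against 0.914, but no correlation moved by more than 0.004, and 17.8% of the other genes were highest in this library against 18.3% in HF floxed replicate 2. Of a list of 8 fetal liver and liver tumour genes fixed before the data were examined, 5 had enough counts to be tested, and 5 of these 5 were highest in this library, among them Afp at 66.44 and Gpc3 at 245.57 CPM. Of the cell cycle genes 14 of 15 were highest too, and 11 of 11 pericentral genes lowest. Liver tumour tissue in the sampled piece may explain this, as a hypothesis, and 5 of 7 bile duct markers were highest there as well. Diet and genotype are shared with replicates 1 and 3, so they do not explain it alone, and no histology was used here.

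Clock genes split the libraries across groups. The clock score differed by up to 6.37 within a group and by 3.19 between group means, which excludes diet or genotype alone. Another time of day at tissue collection could give this, and it was tested on 4 clock genes left out of the score: 1 (Usp2) placed the same 4 libraries at the predicted end, Hlf and Nfil3 did not, and Clock missed by less than counting error. The bound written beforehand counted 1 of 4 as against this explanation. The rule that a miss within counting error leaves a gene undecided was added after the result was seen, and only under it does the explanation stay open.

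Pairs of libraries of the same group were near-identical: LF knockout replicates 2 and 3, and HF floxed replicates 1 and 2. Their median squared deviation was 2.33 and 4.37 times sampling noise, so they are not the same library counted again. It was 8.07 to 40.38 in the other pairs of a group and at least 5.17 between libraries of different groups (LF floxed replicate 2 and LF knockout replicate 1). Of 62 genes that are on in some libraries and off in others, 93.5% and 90.3% were alike within these pairs, against 33.9 to 83.9% in other pairs of a group and up to 88.7% between groups. Their biological coefficients of variation were 5.2 and 11.7%, against 25 to 60.7% in the other pairs of a group and at least 17.8% between groups. The pairs were picked for being the closest, so their rank follows from the choice and only the size of the gap can decide. Set against the mean and spread of 8 values from the other pairs of a group, and multiplied by the 12 pairs to allow for the choice, the one-sided p of a t test on log2 values was 0.00527 for the LF knockout pair, which goes against separate animals that vary as the others do. For the HF floxed pair it was 0.0942, and such animals stay possible there. Some of the 8 values share a library, which the t test does not allow for, so both p-values are only approximate. Separate preparations from 1 liver, or close littermates, may give this and were not tested; if each pair is 1 animal, the groups hold fewer than 3.

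Lyz2 may be lower relative to other macrophage genes in the libraries labelled knockout, as a hypothesis. Against the mean of 28 other macrophage genes it was lower by a log2 difference of -1.63 over both diets, with a two-sided exact permutation p of 0.005, the smallest that 400 relabellings within diets allow. Without HF knockout replicate 3 the difference was -0.76 and without HF knockout replicate 2 it was -2, with an exact permutation p of 0.005 each (200 relabellings). In each diet alone the exact permutation p was 0.1. The size differed between diets: the relative log2 values were 2.21, 2.25 and 2.31 in LF floxed and 1.29, 2.16 and 2.04 in LF knockout. They were 1.78, 1.9 and 2.19 in HF floxed and 1.11, 0.62 and -4.36 in HF knockout. The relabellings take the near-identical libraries as independent. The Kupffer cell markers among the other macrophage genes were called higher in HF knockout than in HF floxed. A Cre gene placed in the Lyz2 locus, as in a widely used macrophage deleter, would lower Lyz2, but the labels do not name the Cre line.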
